A study of Homo sapiens with 12 samples.

How the data were processed

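The series holds 12 eCLIP libraries, of HEK293T cells per the labels' protocols, of which the 6 immunoprecipitation libraries were analysed here and the 6 inputs enter only through the authors' fold values. Per the labels' protocols, cells were transfected with 10 µg of plasmid for myc-QKI-5 or its double substitution mutant and cultured for 72 hours, or left unmodified, then crosslinked at 254 nm with 400 mJ/cm2. Anti-MYC antibody was used for the tagged proteins and anti-QKI antibody for the endogenous protein, so antibody and transfection both differ between the tagged and endogenous groups. Libraries were grouped by their titles, with 2 per group.

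Per the submitters' processing notes, the reads were handled with UMI-tools, cutadapt, STAR and SAMtools on build hg19. Versions and the peak caller are not given in the sources used here. Clusters were called in each library, and per the file headers they are input-normalized. Each deposited cluster carries the authors' log2 fold of immunoprecipitation over its size-matched input. Each also carries the authors' −log10 p of that enrichment, capped at 400. The myc tracks have a deposited browser score that marks clusters past both thresholds. The deposited per-library myc lists hold only clusters with a log2 fold above 0, while the endogenous lists keep 155229 and 33333 clusters at or below 0. A missing myc cluster is therefore either absent or not above input. The authors' reproducible lists pool the 2 libraries of a group, and every peak in them has a log2 fold above 3. The fold and −log10 p of a reproducible peak are the authors' values for the pair.

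Read depth per library is not given in the sources used here. Clusters per library were 226962 and 273269 in wild type, 231814 and 272728 in the mutant, and 384347 and 231844 in endogenous. Because the depth is unknown and many clusters rest on few reads, low folds are coarse. Binomial intervals are exact Clopper-Pearson intervals at 95% and cover counting error only.

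Gene names and transcript regions came from the annotation in the endogenous files, where 98.2% of 616191 clusters received 1 gene name. Clone, microRNA and lnc- names were dropped where another name remained, and clusters with several names left were not named, a rule set after the annotation had been inspected. Myc clusters took the name and region of the endogenous cluster with the longest overlap on the same strand. Coordinates are 1-based hg19 positions from the files.

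Peaks overlapped when they shared at least 1 base on the same strand. Overlap between groups was set against all clusters found in both libraries of a group, as planned, and also against those that did not overlap its reproducible peaks, a narrower background that departs from the plan. Over all clusters the background was 11.98% for wild type in endogenous and 0.160% for mutant in wild type. Means per library were compared with exact two-sided permutation tests, and counts with two-sided Fisher's exact tests adjusted by Benjamini-Hochberg. For single regions, clusters of the 4 myc libraries were merged into 778449 regions, the cluster with the highest −log10 p was taken per library, and the 5481 regions with a cluster in all 4 were tested with limma's lmFit and eBayes. Adjusted p-values for regions are from limma.

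The limma step was tested on simulated data for wild type against mutant over 5481 regions, with 50 regions shifted at each size. It called 0% of regions shifted by a log2 value of 1, 2% at 2, 50% at 3 and 86% at 4, and 1 of 5281 unshifted regions. The sign was right for 88% at a shift of 1 and for 100% at the larger shifts, and a shift of 1 was left out of the pass condition of the test once this had been seen. Overlap counts were checked against bedtools.

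Apart from the narrower overlap background and the classes of enriched peaks, which were set against the other clusters of a library where all clusters had been planned, the groups, the main tests, the gene lists and all settings not named as chosen later were fixed before the data were examined. The 8 lists were U6 and other small nuclear RNA genes, tri-snRNP and U6 protein genes, splicing regulators, known QKI targets, cardiac sarcomere and calcium handling genes, nuclear long noncoding RNAs, replication-dependent histone genes, and neuronal markers as a cell type foreign to this line. The histone list took names by prefix and so also holds H2AFV, a replication-independent variant. Genes named were, per group, those of the 10 reproducible peaks with the highest fold (1 per gene) and the 10 genes with the most peaks, then the 8 largest and up to 4 most negative regions past limma's threshold, and up to 8 members of each list by number of peaks, of which only the leading ones are printed for most lists. All mutant genes were to be named if there were 15 or fewer, but there were 19, so the leading 10 were. Only 1 region passed in the negative direction. FOXO1, RNU6-8, single tRNA genes beyond this rule and the classes at endogenous loci were chosen after values were seen. The values of 1 list member are not reported here.

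Alternatives were other thresholds, other overlap rules, missing clusters set to 0, centring, another background for lists, and leaving out each library. The stricter reproducible list used the median −log10 p over all 3 lists. Motif content around peaks was not analysed here, since it needs the hg19 sequence. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, bedtools 2.31.1, R 4.3.3 and limma 3.58.1.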

Results

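QKI (Quaking) is a KH-domain RNA-binding protein that regulates pre-mRNA splicing. Its RNA contacts were mapped by enhanced crosslinking and immunoprecipitation (eCLIP), in which UV-crosslinked protein is pulled down and the attached RNA is sequenced beside a size-matched input. The sample labels name the cells HEK293xT and their protocols HEK293T, an established human embryonic kidney line, and these labels were followed. The series' design note speaks instead of human embryonic stem cells during cardiomyocyte differentiation, a conflict that the files do not settle. Anti-MYC libraries came from cells expressing myc-tagged QKI-5, either wild type or with the substitutions K120A and R124A (numbered by residue), and anti-QKI libraries came from unmodified cells. Each of the 3 groups had 2 immunoprecipitation libraries, called wild type, mutant and endogenous here. Between 226962 and 384347 clusters per library carried a log2 fold over input and a −log10 p. A cluster was called enriched at a log2 fold of at least 3 and a −log10 p of at least 3. With 2 libraries against 2, the smallest p that an exact two-sided permutation test can give is 0.333. The labels do not say whether the libraries of a group came from separate cultures, so p-values across libraries measure only the spread between these libraries, which may be technical.

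The first question was how many enriched peaks the tagged protein had once the KH-domain residues were substituted. The amounts of wild type and mutant protein expressed or pulled down were not analysed here. Differences between wild type and mutant are therefore not scaled to the amount of protein. Wild type QKI-5 had 4698 and 5171 enriched peaks (4934 ± 334, SD, n = 2), and the mutant had 94 and 829 (461.5 ± 519.7, SD, n = 2). The ratio of the means was 10.7, and the poorer wild type library held 5.67 times as many as the richer mutant library. As a share of all clusters, 2.07% (95% exact interval 2.01 to 2.13) and 1.89% (1.84 to 1.94) were enriched in wild type, against 0.0405% (0.0328 to 0.0496) and 0.304% (0.284 to 0.325) in the mutant. Endogenous QKI had 16231 and 12504 enriched peaks, 4.22% and 5.39% of its clusters. The myc files list only clusters above a log2 fold of 0, and over such clusters the endogenous shares were 7.08% and 6.30%. The authors' reproducible lists held 3671 wild type peaks at 2045 named genes, 55 mutant peaks at 19 genes and 12409 endogenous peaks at 3930 genes, each list being 1 set for a pair of libraries and so without a replicate error.

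Both wild type libraries lay above both mutant libraries, with an exact two-sided permutation p of 0.333, the smallest possible. The size of the ratio rested on single mutant libraries: it was 5.95 without mutant library 1 and 52.5 without mutant library 2. It was 4.79 at a log2 fold of at least 2, 25.5 at a log2 fold of at least 4, 21.9 at a −log10 p of at least 5, and 30.7 when clusters away from any annotated endogenous cluster were left out, a setting added after the data were seen.

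**Figure D1:**
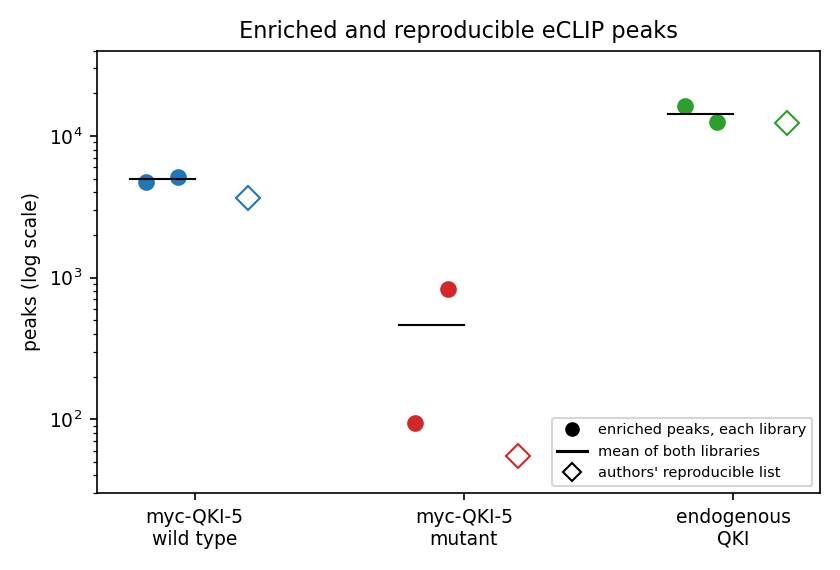
Enriched peaks in each eCLIP library (filled circles, n = 2 per group), their mean (line) and the number of peaks in the authors' reproducible list (open diamond), on a log axis. Mutant libraries, at 94 and 829 peaks, lie below the wild type libraries at 4698 and 5171 and the endogenous libraries at 16231 and 12504.

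The second question was whether tagged and endogenous QKI were found at the same places. The wild type peak with the highest fold lay in an intron of MICAL3, which encodes an actin-oxidising monooxygenase (hg19 chromosome 22, 18359786 to 18359817, minus strand). Its log2 fold was 9.54 and 8.57 in the wild type libraries and 9.18 and 8.69 in the endogenous libraries, and no mutant library listed a cluster there. MICAL3 also held the most reproducible peaks in both lists, 30 in wild type and 48 in endogenous. An intron of RAB7A, a late endosomal GTPase gene, followed (chromosome 3, 128471073 to 128471155, plus strand), at 9.51 and 9.44 in wild type, 9.48 and 9.64 in endogenous, and 1.93 and 1.98 in the mutant.

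Of the 3671 wild type reproducible peaks, 2504 (68.2%, 66.7 to 69.7) overlapped an endogenous reproducible peak by at least 1 base on the same strand, against 11.98% of all clusters found in both wild type libraries, or 8.94% of those away from the wild type reproducible peaks. Fisher's exact test across peaks, which are not replicates, gave an odds ratio of 15.8 against all such clusters and 21.9 against the narrower background, each with a p too small for the software to represent. In the other direction 24.3% of endogenous peaks overlapped a wild type peak, against 4.67% of all clusters and 1.30% of those away from endogenous reproducible peaks. Within groups, 57.9% and 53.4% of enriched wild type peaks overlapped an enriched peak of the partner library, 67.0% and 77.5% did so in endogenous, and 35.1% and 4.10% in the mutant.

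Other leading wild type peaks were in introns of KDM5A, which encodes a histone H3 lysine 4 demethylase (9.21 and 8.58), of SLC7A11, the cystine transporter gene (7.36 and 8.67), of COL13A1, a transmembrane collagen gene (7.22 and 7.67), and of ZNF423, a zinc finger gene (7.72 and 6.88). The 3′ UTRs of LRRC3DN (7.54 and 9.28) and TTF2 (7.23 and 8.46) were among them too, and had the highest folds in endogenous, at 10.63 and 10.65 for LRRC3DN. In endogenous, introns of ZNF12 (9.27 and 9.42), LYRM4, an iron-sulfur cluster assembly gene (8.81 and 9.16), and NBPF1 (8.77 and 8.83) followed, with the 3′ UTR of HNRNPK, which encodes an hnRNP splicing factor (7.45 and 8.54). After MICAL3, the endogenous genes with the most peaks were SLIT2, an axon guidance ligand gene, with 46, FHIT with 45, INPP5A and CMSS1 with 38 each, ROBO1, the SLIT receptor gene, with 34, and GMDS, ANKRD17 and LINC00669 with 32 each. RAD51B had 30. In wild type the counts were 9 for SLIT2, 9 for FHIT, 2 for INPP5A, 3 for CMSS1 and 3 for ROBO1. The wild type list also had 13 peaks in the noncoding transcript lnc-USP6-2, 11 in MT-ND5, 10 in AC009262.2, and 8 each in FAM157A, G2E3 and NLGN1. DNAJB6, a co-chaperone gene, ran the other way, with 11 wild type peaks and 3 endogenous peaks, a difference that was not tested.

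The third question was how far the mutant retained signal at sites defined without it. At the 12409 endogenous reproducible peaks, which were made from other libraries, the median log2 fold was 2.55 ± 0.04 in wild type and 0.84 ± 0.01 in the mutant (SD, n = 2 each). The difference of 1.72 was larger than the spread between libraries, with an exact permutation p of 0.333. A cluster was listed at 83.1% ± 2.48 of these peaks in wild type and at 10.1% ± 0.251 in the mutant, and 27.0% ± 2.01 against 0.222% ± 0.0171 were enriched. At the wild type reproducible peaks, which were chosen on the wild type libraries and so do not test the difference independently, the medians were 3.92 and 1.10. Medians cover only the listed clusters, and the myc files list none with a log2 fold of 0 or below. With missing clusters set to 0, the differences were 2.23 at endogenous and 3.92 at wild type peaks.

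Introns made up 8170 of the 9650 merged endogenous loci, and 25.8% and 23.6% of them were enriched in the wild type libraries against 1 and 5 loci in the mutant libraries (0.0122% and 0.0612%). At 171 loci on 5′ splice sites, 45 and 36 were enriched in wild type and 0 in both mutant libraries, a share of up to 2.13% by the exact interval. At 163 loci on 3′ splice sites the counts were 54 and 42 against 0 and 1, and at 343 loci in 3′ UTRs 126 and 122 against 2 and 1. Among 20 mitochondrial loci, 18 and 19 were enriched in wild type and 0 in both mutant libraries.

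U6 small nuclear RNA genes and their pseudogene copies, which encode or resemble the spliceosomal RNA that pairs with the 5′ splice site, stood apart from these classes. Of 15 U6 loci, 14 were enriched in each endogenous library, 8 and 4 in the wild type libraries, and 6 and 5 in the mutant libraries. The loci were chosen on the endogenous libraries, so the endogenous share is high by construction, as it was for introns (88.8% and 90.4%). In at least 1 mutant library, 7 of 15 U6 loci (46.7%, 21.3 to 73.4) were enriched against 11 of the 9635 other loci (0.114%). Fisher's exact test across loci gave an odds ratio of 766 and p = 1.32e-16 (1.05e-15 after Benjamini-Hochberg adjustment over 8 tests), in a comparison chosen after the data were seen. At a log2 fold of at least 4 the count was 4 of 15 U6 loci against 5 of 9635. U6 copies are nearly identical in sequence, so which copy a read came from is uncertain.

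**Figure D2:**
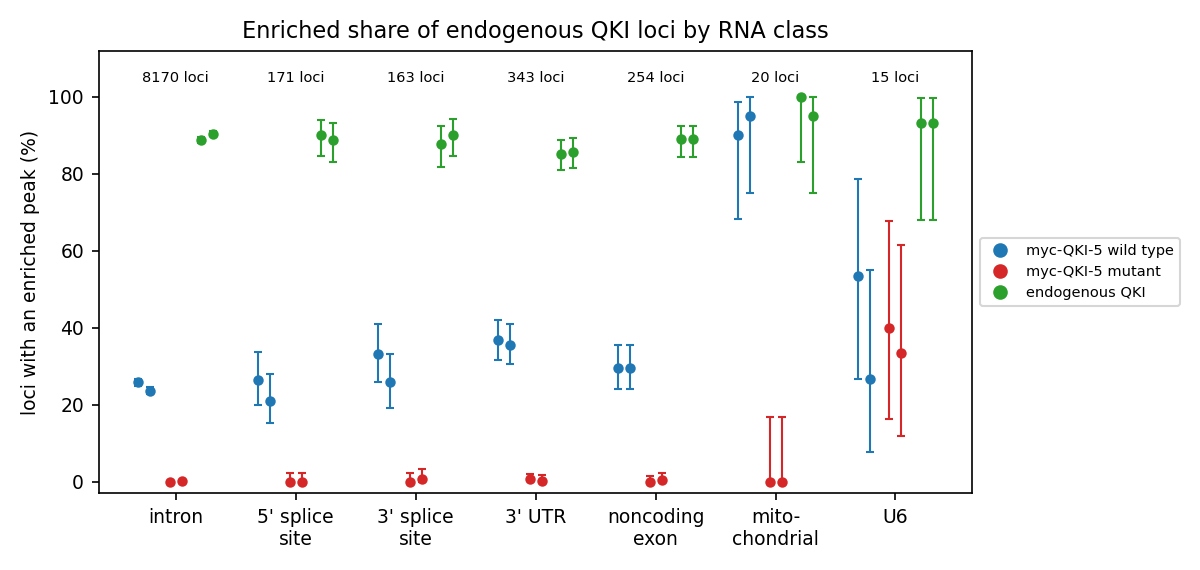
Share of merged endogenous QKI loci with an enriched peak, by RNA class (percent, points for each library, bars for 95% exact binomial intervals, number of loci above each class). Mutant points lie near 0 in every class shown except U6, where 6 and 5 of 15 loci were enriched. Endogenous points are high by construction, since the loci were chosen on the endogenous libraries.

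The fourth question was which peaks the mutant had. Its highest fold was in an intron of ARHGAP24 (chromosome 4, 86875798 to 86875813, plus strand), with a log2 fold of 7.54 and 6.15 in the mutant, 8.56 and 7.74 in wild type, and 7.36 and 6.58 in endogenous. An intron of LINC00471 reached 6.21 and 3.91 in the mutant and 6.78 and 6.01 in wild type. Among U6 copies, RNU6-671P had 4.05 and 5.51 in the mutant (6.12 and 5.80 in wild type), RNU6-40P 3.82 and 4.86 (4.08 and 3.28), RNU6-49P 4.41 and 4.19 (5.68 and 4.19), and RNU6-44P 4.31 and 4.27 (4.37 and 3.61). The arginine tRNA gene tRNA-Arg-TCG-1-1 had 4.50 and 4.13 in the mutant and 3.89 and 1.97 in wild type, and was below input in endogenous, at −0.35 and −0.55. For tRNA-Arg-TCT-1-1 the values were 4.41 and 2.72 in the mutant, 3.91 and 2.39 in wild type, and −0.35 and −0.78 in endogenous. An intron of ANKRD30BL held 6 mutant peaks, the most of any gene, beside 2 wild type peaks and 1 endogenous peak. Its leading mutant peak was at 3.16 and 3.98 in the mutant, 3.87 and 4.32 in wild type, and 0.76 and 2.37 in endogenous. An intron of PID1 was at 4.07 and 4.11 in the mutant, 2.00 and 3.61 in wild type, and −0.74 and 1.15 in endogenous.

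Of the 55 mutant reproducible peaks, 20 (36.4%, 23.8 to 50.4) overlapped a wild type reproducible peak, against 0.160% of all clusters found in both mutant libraries and 0.119% of those away from the mutant reproducible peaks. Fisher's exact test across peaks gave an odds ratio of 356 against the former (p = 6.33e-41) and 481 against the latter (p = 3.48e-43). In addition, 17 of 55 overlapped an endogenous peak (Fisher's exact test, odds ratio 83.1 against all such clusters, p = 2.37e-25), and 17 lay away from any annotated endogenous cluster. The 55 peaks merged into 35 loci when peaks within 50 bases were joined. The interval and the p-values of these tests count neighbouring peaks of 1 locus separately. Of the 829 enriched peaks of mutant library 2, 589 lay away from any annotated endogenous cluster and 72.9% had a −log10 p under 5, against 32 of 94 and 38.3% in mutant library 1.

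The fifth comparison tested single regions with limma over the 4 myc libraries. Of 5481 regions with a cluster in all 4, 36 were higher in wild type and 1 was lower at a Benjamini-Hochberg adjusted p of at most 0.05. The largest differences were in introns of AC009262.2 (log2 difference 7.58, SE 0.57, limma adjusted p = 0.00183) and RAB7A (7.52, SE 0.47, adjusted p = 0.00113), followed by the 3′ UTR of FHL1, a LIM-domain protein gene (6.19, SE 0.49, adjusted p = 0.00183). Introns of MRPL34, a mitochondrial ribosomal protein gene (5.96), GPHN, the gephyrin gene (5.80), LYRM4 (5.42) and ZNF12 (5.39) came next, then the coding region of MT-ND5, a respiratory complex I gene (5.11). Of the 36 regions, 25 were in introns of coding genes, 5 in 3′ UTRs, 3 mitochondrial and 3 in the introns or exons of other noncoding transcripts, and 35 lay at an endogenous reproducible peak. The region lower in wild type was on chromosome 9, 140610761 to 140610864, plus strand, with no gene name in the files (difference −3.35, SE 0.55, limma adjusted p = 0.0451). Its call ended without mutant library 1 (limma adjusted p = 0.0895), without mutant library 2 (0.183) and with robust eBayes (0.0504). Without mutant library 1 the calls for GPHN, LYRM4, ZNF12 and MT-ND5 ended, and without mutant library 2 those for AC009262.2, GPHN, ZNF12 and MT-ND5.

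The fixed gene lists had 0 regions past the threshold in limma's test over all regions, where 280 regions were higher and 398 lower in wild type at an unadjusted p under 0.05. This balance turned with the setting, to 439 higher and 203 lower in limma after centring of each library. It was 223 and 206 without wild type library 1, 231 and 149 without wild type library 2, 184 and 121 among 1253 regions past a filter on −log10 p, and 236 and 47 among the 1701 regions of the fit with a spread shared by all 6 libraries. Adjusted over the list alone, 1 region was higher in wild type, at FOXO1 among the known QKI targets, and every other list stayed at 0. The median difference was −0.04 over 14 U6 regions (7 of them positive), 0.07 over 28 regions of known QKI targets, −0.05 over 49 regions of splicing regulators, −0.25 over 33 of nuclear long noncoding RNAs, −0.27 over 4 of tri-snRNP and U6 protein genes, −0.49 over 2 of cardiac genes and −0.80 over 4 of histone genes, while no neuronal marker had a tested region. The median over all regions was −0.26, and 0.01 after centring. Tested regions needed a listed cluster in both mutant libraries, so sites lost in the mutant are left out of these medians. At the 280 tested regions on an endogenous reproducible peak the median difference was 1.35, with 250 positive. At the 98 on a wild type reproducible peak, a list chosen on the wild type libraries, it was 2.95, with 96 positive. The number past the threshold fell from 37 to 4 without mutant library 1 and to 4 without mutant library 2, and was 73 without wild type library 1 and 58 without wild type library 2. It was 0 with missing clusters set to 0, and 84, 74 and 72 under a spread shared by all 6 libraries, a filter on −log10 p and centring of each library.

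In which part of the transcript the peaks lay was compared with all other annotated clusters of the same library. Coding introns held 80.0% ± 0.78 of annotated enriched peaks in wild type, 83.7% ± 0.089 in endogenous and 39.7% ± 26.4 in the mutant (SD, n = 2 each; exact permutation p = 0.333 for wild type against mutant). The 2 mutant libraries lay far apart, at 21.0% and 58.3%. Among the other annotated clusters the share was 79.1% and 80.5% in the wild type libraries, 79.1% and 78.2% in endogenous, and 70.2% and 67.1% in the mutant. For distal introns alone the odds ratios were 0.931 and 0.891 in wild type (adjusted Fisher's exact p = 0.0501 and 0.000715, so that only library 2 passed the threshold), while in endogenous they were 0.993 and 1.08 (adjusted p = 0.781 and 0.000232). Peaks on 3′ splice sites were over-represented in both wild type libraries (odds ratios 1.82 and 2.23, adjusted Fisher's exact p = 1.34e-06 and 1.97e-11) and both endogenous libraries (1.87 and 1.44, adjusted p = 2.54e-18 and 8.61e-06). Introns near splice sites were over-represented as well (1.20 and 1.27 in wild type, 1.58 and 1.45 in endogenous), and coding exons were under-represented (0.504 and 0.428, and 0.199 and 0.156). In the mutant libraries, introns near splice sites had odds ratios of 0.482 and 2.48 (adjusted Fisher's exact p = 0.372 and 1.17e-06). Coding exons had 0.270 and 0.300 there (adjusted Fisher's exact p = 0.361 and 0.000599). On 5′ splice sites the odds ratios were 1.05 and 1.16 in wild type (adjusted Fisher's exact p = 0.781 and 0.346) and 1.38 and 1.09 in endogenous (6.36e-06 and 0.361). In both mutant libraries tRNA genes were over-represented (6 of 62 and 12 of 240 peaks, odds ratios 125 and 86.9, adjusted Fisher's exact p = 2.14e-10 and 1.22e-17). Noncoding exons were over-represented there too (10.6 and 2.57, adjusted Fisher's exact p = 1.93e-12 and 7.32e-05), while distal introns were under-represented (0.125 and 0.455, adjusted p = 5.09e-12 and 7.30e-09). Transfer RNA genes were over-represented in wild type library 1 too (12 of 4519 peaks, odds ratio 6.32, adjusted Fisher's exact p = 8.94e-06), while wild type library 2 had 0 of 4745. These tests count several peaks of 1 tRNA gene separately. By the cluster with the highest −log10 p at each locus, only 3 and 4 of 53 tRNA loci were enriched in the mutant libraries. In the wild type libraries 5 and 0 were. Clusters are not replicates, and myc clusters were annotated only where an endogenous cluster overlapped them, for 96.2% and 91.8% of enriched wild type peaks but 66.0% and 29.0% of mutant peaks. Of all clusters, 39.7% and 34.9% were annotated in the wild type libraries and 19.7% and 19.5% in the mutant libraries. The myc odds ratios thus cover only clusters at endogenous ones, a larger part of the enriched peaks than of the background.

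Gene lists fixed in advance were counted among genes with a reproducible peak. Of 37 known QKI targets with a cluster in both wild type libraries, 20 had a wild type peak (54.1% against 20.4% of all such genes, odds ratio 4.62, adjusted Fisher's exact p = 4.93e-05), and 33 of 41 had an endogenous peak (80.5% against 33.0%, odds ratio 8.44, adjusted p = 6.32e-09). Both calls ended when drawn lists were matched on the number of clusters per gene (adjusted p = 0.842 in wild type and 0.188 in endogenous). Apart from MICAL3, the targets with a peak included the microtubule-binding protein genes CLASP2 (4 wild type and 15 endogenous peaks) and CLASP1 (1 and 11), ERBB2IP (3 and 13), DST (1 and 10) and MAP4K4 (1 and 9). QKI's own transcript had 5 wild type peaks, the highest in its 3′ UTR at a log2 fold of 6.25, and 9 endogenous peaks. Among splicing regulators, 27 of 49 had an endogenous peak (odds ratio 2.50, adjusted Fisher's exact p = 0.0117, but 1 with matched lists), with 17 peaks in MATR3, 17 in PCBP2, 13 in RBFOX2 and 12 each in HNRNPK and MBNL1. In wild type 16 of 51 had one (adjusted Fisher's exact p = 0.225). Nuclear long noncoding RNAs had a peak in 9 of 12 cases in endogenous (adjusted Fisher's exact p = 0.0170, but 0.455 with matched lists), among them FTX, JPX and MIAT, and in 4 of 12 in wild type (adjusted Fisher's exact p = 0.749).

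The list of U6 and other small nuclear RNA genes was the only list past the threshold in the mutant, with 5 of 16 genes against 0.230% of all genes (odds ratio 267, adjusted Fisher's exact p = 3.74e-09). All 5 were U6 genes or copies: RNU6-671P, RNU6-40P, RNU6-49P, RNU6-44P and RNU6-8. In wild type 4 of 25 and in endogenous 15 of 40 had a peak (adjusted Fisher's exact p = 1 for both). Tri-snRNP and U6 protein genes had a peak in 2 of 24 cases in wild type and 8 of 23 in endogenous, cardiac sarcomere and calcium genes in 3 of 21 and 14 of 28, replication-dependent histone genes in 4 of 13 and 1 of 5, and neuronal markers in 0 of 3 and 0 of 2, none past the threshold. Every list other than the small nuclear RNA list had 0 genes with a mutant peak. With lists matched on the number of clusters per gene, the mutant small nuclear RNA call stood (adjusted p = 0.0024) and the endogenous one passed (0.0024, 15 genes against a matched median of 2). Against genes with a cluster in any library, the mutant call also stood (odds ratio 55.8). The endogenous list was instead under-represented there (odds ratio 0.514, adjusted Fisher's exact p = 0.0339), so its direction depended on the background.

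**Figure D3:**
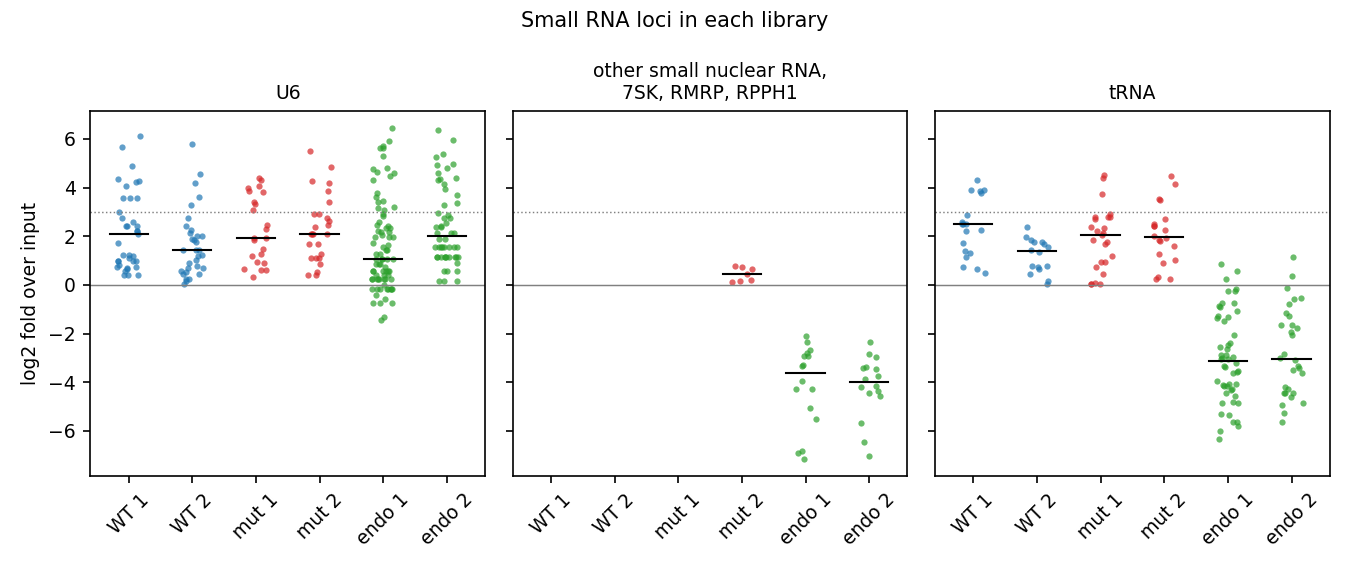
Log2 fold over input at U6 loci, at loci of other small nuclear RNAs, 7SK, RMRP and RPPH1, and at tRNA loci (points for loci with a listed cluster, line for the median, dotted line at the fold threshold of 3) in each wild type (WT), mutant (mut) and endogenous (endo) library. The myc files hold only values above 0. U6 loci reach above 3 in every library, and the other small nuclear RNA loci lie below 0 in both endogenous libraries.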

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

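Of the tests in this part, the ratio of mutant enriched peaks at the stricter fold threshold was fixed before its result was seen, and the others were chosen only after the patterns or closely related values had been seen.

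Transfer RNA loci ran in opposite directions in the tagged and endogenous libraries. Of 12 tRNA loci with a cluster in both mutant and both endogenous libraries, 11 were above input in both mutant libraries and below input in both endogenous libraries, and in wild type the same held for 12 of 13. They were singled out because every library of one group lay on one side of input and every library of the other group on the opposite side, and the difference was not tested. The myc files list no value at or below 0, so a listed tRNA locus is above input there by construction.

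That truncation alone does not account for the pattern. Counted over all 53 tRNA loci, listed or not, the lowest share above input in a myc library was 30.2%, against 5.66% (1.18 to 15.7) in the endogenous library with the higher share. At the 12 tRNA loci with a cluster in all 4 myc libraries, the median wild type minus mutant difference was −0.48, and 10 of the 12 were lower in wild type. A difference this small was predicted for tRNA recovery that wild type and mutant share. Wild type library 1 lay above library 2 at all of these loci except tRNA-SeC-TCA-1-1. The difference thus rests on averaging libraries that disagreed and does not settle whether recovery was shared. Over all tRNA loci listed in a library, the median log2 fold was 2.50 and 1.39 in wild type and 2.07 and 1.95 in the mutant. The tag, the antibody and the transfection go together in this design, so which of them could bring tRNA down was not tested, and unequal input libraries stay open too.

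Of 15 endogenous U6 loci, 6 and 5 were enriched in the mutant libraries, against 1 and 5 of 8170 intron loci. Recovery that extends to U4, U5, U12, U4atac, U6atac, 7SK, RMRP and RPPH1 is argued against, since their 17 loci reached a log2 fold of at most 0.76 in any myc library. Among the myc libraries only mutant library 2 listed any of them, at 7 loci. U1 and U2 are not among these loci, so small nuclear RNA in general was not covered. Most U6 loci are pseudogene copies, however, and recovery of such copies in general stays open. Among 17 pseudogene loci of other small RNAs, only 4 and 1 had a cluster in the mutant libraries, with 0 enriched. RNU1-85P had the highest mutant value, 2.78 in library 1 (−log10 p 1.29), beside 2.50 and 2.61 in wild type, while RNU4ATAC16P had 3.94 and 2.69 in wild type and 1.19 in mutant library 1. One pool of U6 reads spread evenly over near-identical copies would give similar folds at each copy. Folds of U6 loci with a −log10 p of at least 3 had an SD of at least 1.16 in each mutant library. This does not decide the question, since that filter keeps loci with few reads only where their fold is high. Unequal input at each copy may add to this spread. At 14 of 93 annotated U6 loci with a cluster in all 4 myc libraries, the median wild type minus mutant difference was −0.041 (range −0.77 to 1.17, 7 of 14 positive). It was 1.55 at 183 of the 8170 endogenous intron loci, those with a cluster in all 4 myc libraries. The intron loci were limited to endogenous reproducible peaks and the U6 loci were not, so the 2 sets are not alike. Both choices leave out loci missing from a library. At the 14 U6 loci, wild type library 1 lay above library 2 except at RNU6-222P and RNU6-11P, for example 4.22 against 0.70 at RNU6-37P. The small U6 difference therefore rests on averaging wild type libraries that disagreed. Over all U6 loci listed in a library, the median log2 fold was 2.11 and 1.44 in wild type and 1.93 and 2.11 in the mutant. A candidate explanation is that U6 was recovered without the substituted residues, for example through other proteins bound to QKI, and this remains a hypothesis found and tested on the same data.

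Mutant library 2 had 8.82 times as many enriched peaks as mutant library 1, while the wild type libraries differed by a factor of 1.10. Peaks just past the fold threshold do not make the whole difference, since the ratio was 3.97 at a log2 fold of at least 4 (127 against 32). Peaks away from endogenous clusters do not either, since it was 3.87 at annotated endogenous clusters (240 against 62), and library 2 had only 1.18 times as many clusters. Each of these could account for part, and a difference in read depth or input, neither of which was analysed here, stays open. No biological explanation was tested, as the labels give none within a group.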

How the results depend on the processing

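The setting that left out unannotated clusters, the other thresholds for U6 loci and the endogenous share over clusters above input were chosen only after the data were seen. There were 246 alternatives for peak counts, shares, overlaps, list calls and regions past limma's threshold. Of the 72 for named regions, 0 turned a direction. Count ratios, overlaps between groups and numbers past limma's threshold were rated in a way that cannot show a turn. The balance of all regions, which is not among the 246, did turn. Of the alternatives on the results that answer a comparison, 37 were rated as kept and 32 as moved. Of the rest, 120 were rated as kept, 11 lost their call, all of them named regions, and 46 moved. A kept count or ratio lay within a fixed factor of the reported value. A kept overlap between groups or named region only held its call, whatever its size. List calls enter as 1 number, so the 4 that ended with matched lists are not among the 11. The ratio of wild type to mutant enriched peaks, 10.7, was 4.79 at a log2 fold of at least 2, 21.9 at a −log10 p of at least 5, 25.5 at a log2 fold of at least 4 and 30.7 without unannotated clusters, and ranged from 5.95 without mutant library 1 to 52.5 without mutant library 2. The ratio of shares, 11.5, was 5.15, 23.1 and 27.0 under the same 3 thresholds and ranged from 6.52 to 48.9 with 1 library left out. Weak peaks of mutant library 2 entered or left with the threshold.

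The wild type minus mutant difference at wild type peaks, 2.82, was 2.85 with mean cluster values, 3.92 with missing clusters at 0, 2.78 after centring and 3.30 in the upper part of the list. At endogenous peaks, 1.72, it was 1.68, 2.23, 1.68 and 2.08 under the same settings. The wild type intron share, 80.0%, was 77.3% at a −log10 p of at least 5, 79.0% at a log2 fold of at least 4 and 76.7% with 1 peak per gene and class. The number of list calls, 5, was 2 with matched lists and 10 against genes with a cluster in any library. Some of these 10 were under-representation. The small nuclear RNA list had odds ratios of 0.269 in wild type and 0.514 in endogenous, and the histone list 0.0865 in endogenous. The cause of these shifts was not tested.

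The number of regions past limma's threshold, 37, was 84 when all 6 libraries shared a spread (1701 regions), 74 among 1253 regions with a −log10 p of at least 3, and 72 after centring (71 higher, 1 lower). Centring moved the median difference of all regions from −0.26 to 0.01, and the regions at an unadjusted p under 0.05 in limma from 280 higher and 398 lower to 439 and 203. With 6 libraries sharing a spread the median was 0.03, with 236 higher and 47 lower. More were higher than lower also under the −log10 p filter (184 and 121) and without wild type library 1 (223 and 206) or 2 (231 and 149). With missing clusters at 0 it was 0 of 778449 regions in limma, where 36872 were higher and 13545 lower at an unadjusted p under 0.05. Leaving out 1 library, with the lone library assumed to vary like the other group, gave 4 to 73. Of 72 alternatives for the 9 named regions, 11 lost the call and 10 of these left out a mutant library. With the replicate number as a block, 42 regions passed. Libraries with the same number did not deviate together across the 5481 tested regions (r = −0.04). This does not settle whether they were prepared together, which the labels do not say. With robust eBayes 32 were higher and 0 lower. Motif settings were not run, since they need the hg19 sequence. Depth was not known, and the simulated shifts put most differences under a log2 value of 3 out of reach of the test.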

Other observations

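The comparisons of mitochondrial peaks in this part were chosen only after the data were seen, while the test of transcript regions in each library was planned.

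Mitochondrial transcripts carried peaks in both wild type and endogenous libraries. The reproducible lists held 41 wild type and 46 endogenous peaks on the mitochondrial genome, all of them on the plus strand, and 0 mutant peaks. MT-ND5, a subunit gene of respiratory complex I, carried 11 wild type and 12 endogenous peaks, with the highest wild type peak (13678 to 13723, plus strand) at a log2 fold of 7.15 and 7.29 in wild type and 8.68 and 8.40 in endogenous. At the same place mutant library 2 had a log2 fold of 1.45 and mutant library 1 listed no cluster. Mutant library 1 had 7 enriched mitochondrial peaks, 3 on the plus and 4 on the minus strand, and mutant library 2 had 0. None of the 20 mitochondrial endogenous loci was enriched in either mutant library, although 2 and 16 of them had a cluster.

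Among cardiac genes, TPM1, which encodes a tropomyosin, had 6 endogenous peaks, the highest in an intron at a log2 fold of 7.47, and 1 wild type peak at 5.21. CAMK2D, a calcium/calmodulin-dependent kinase gene, had 5 and 3, with the highest at 6.54 and 5.63. Among tri-snRNP genes, SNRNP40 had 4 endogenous and 3 wild type peaks, at up to 5.15 and 5.02. The long noncoding RNA MIAT reached 8.30 in endogenous and 7.52 in wild type.

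In mutant library 2, 19 of 240 annotated enriched peaks (7.92%, 4.83 to 12.1) lay on 5′ splice sites, an odds ratio of 4.70 against its other annotated clusters (adjusted Fisher's exact p = 4.53e-07), while mutant library 1 had 0 of 62 (up to 5.78%). None of the 38 annotated mutant reproducible peaks lay on a 5′ splice site. Of the 17 mutant reproducible peaks away from annotated endogenous clusters, 6 lay on chromosome X between 139805573 and 139807679 on the plus strand and 3 on chromosome 7 between 69961352 and 69961796 on the plus strand. The tRNA gene tRNA-SeC-TCA-1-1 held 4 mutant peaks.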
